A study of Arabidopsis thaliana with 8 samples.

How the data were processed

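Genomic DNA of Arabidopsis thaliana was hybridized to 8 Agilent 2-colour arrays, 3 with Col-0 DNA in both channels and 1 each for mag2-2, rot3-1, zig-2, Ler and a digest mixture of Col-0. Per the labels, Cy3 carried Col-0 DNA on each array and Cy5 carried the DNA the array is named for, and no array had the dyes swapped. Groups were taken from the labels. Each array had 45014 spots, of which 2517 were controls and 42497 were genomic probes. Of the probes, 42147 were 60 bases long, the shortest had 45, and 205 shared their sequence with another probe.

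Per the file headers, the authors extracted spot signals with Agilent Feature Extraction 9.1, which subtracted background, detrended each array in space and by a multiplicative term, and applied a linear dye normalization. The processed and raw spot signals are intensity values, per the file headers, with low processed values replaced by a surrogate. The deposited ratios are log10 values of Cy5 over Cy3. The deposited series table was checked to differ from the ratios in the array files by at most 0.005. The remaining columns used, other in kind, are flags of 0 or 1 per spot as deposited, such as well above background, saturated or outlier. Per the file headers, the mag2-2 array was merged from scans at different intensities.

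The main value was log2 of the Cy5 over the Cy3 processed signal, centred on the median of each array. Control spots were left out, as were spots marked as outliers in either channel, between 0 and 426 probes per array. Saturated spots were kept. A probe was called lower at or below -1 and higher at or above 1. A run was 2 or more neighbouring probes on a chromosome with the same call, and its background was the number of runs in 1000 random reorderings of the array's probes. A probe counts as at background in Cy5 where it was not marked well above background or its processed signal did not pass the 95th percentile of the negative control spots, a level chosen after the values were seen. Its fold was computed against that level and is given as a lower bound. Bins were 1 Mb wide. Intervals are 95% Wilson intervals and cover counting over probes only. Percentiles came from 10000 random probe lists of the same size, matched on decile of Cy3 signal over the self arrays. The thresholds, the gene lists, the tests and most alternatives were chosen before the data were examined, except where stated.

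The depth is given as signal over negative control spots, which in Cy3 was 15.9 to 19.8 on the self arrays, 2.82 on mag2-2, 25.6 on rot3-1, 27.6 on zig-2, 31.2 on Ler and 34.1 on the digest array. The number of arrays limits the precision. The self arrays shared a slide, as did rot3-1 with zig-2 and Ler with the digest array, and mag2-2 lay on a slide of its own. No slide held both a self array and another group.

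The build behind the probe positions is not given in the sources used here. It was tested from the data by sliding the GC content of the probes along the gene bodies of the annotation, in windows of 1 Mb with at least 100 probes. In 53 of 118 windows the best match lay within 200 bp of no shift with a z score of at least 3. These windows held 19993 probes. In the others the positions were shifted or undecided. Genes are named in the matching windows, from probes at least 200 bp inside the gene on both sides, which gave 7978 probes in 6298 genes. The exception is the closing observations, where MAG2, ZIG and the number of genes in their stretches are placed in 2 windows that do not match, at the best shift of each. No other position was converted. This rule for naming was set after the files were seen. The computation was checked on 12 windows of chromosome 4, whose positions were moved by known amounts. All 12 shifts were recovered within 200 bp. These windows matched near no shift beforehand, so this outcome was fixed in advance. It does not test the windows that are shifted or undecided.

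The named genes followed a rule: on mutant arrays, the targeted gene and each gene with a probe in a called run; on Ler, genes in the 15 longest lower and 5 longest higher runs, each member with a probe of a list of 24 natural variation genes, and the 3 genes with the lowest median in each gene class; on the digest array, the 5 highest and 5 lowest medians among genes with at least 2 probes. Some genes that this rule selects are not reported here. The rule foresaw class keywords in gene descriptions. The annotation holds none, so keywords were applied to symbols and synonyms, and EDR2, ADF11, HCAR and AT5G20840 belong to their classes by a word in the name alone. The class of organelle loci on chromosome 2 could not be placed.

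Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. The alternatives were other thresholds and run lengths, normexp background correction with an offset of 50, loess, the deposited series table, a filter on dim probes, subtraction of the self mean with each self replicate left out in turn, limma with the spread pooled from the self arrays, and other centromere widths. The limma fit assumes that a lone array varies like the self arrays, with 2 residual degrees of freedom. In a test on data simulated with the spread of the self arrays, which does not test that assumption, it recovered 97.5% of 200 probes set to -1.5, with 0 false calls, and the run calling found 58 of 58 runs of 2 probes set to -4 in a permuted self array. Recovery of runs nearer the threshold was not simulated. The limma calls used an adjusted p of at most 0.05 and the same size threshold. The robust SDs were 0.10 on rot3-1, 0.14 on zig-2, 0.21 on mag2-2 and 0.27 on Ler, against 0.10 to 0.13 on the self arrays. These are spreads over probes, whereas limma pools the spread of each probe between the self arrays, with a median SD of 0.05. They therefore do not test the assumption. It was not shown to hold on rot3-1, zig-2, mag2-2 or Ler, so the limma counts of these arrays are not read. Fragment lengths around probes and matches of probes to the genome were not analysed here.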

Results

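Genomic DNA of Arabidopsis thaliana was compared by 2-colour comparative genomic hybridization on an Agilent oligonucleotide array with 42497 genomic probes, most of them 60 bases long. The median distance between neighbouring probes was 2407 bp, and positions are given in the numbering of the array files. Every array carried DNA of the reference accession Col-0 in the Cy3 channel. The Cy5 channel held Col-0 DNA again on 3 self arrays and, on 1 array each, DNA of the mutant lines mag2-2, rot3-1 and zig-2, DNA of the accession Ler, and a mixture of differently digested Col-0 DNA. Labelling used 1 µg of DNA, except on the rot3-1 and zig-2 arrays, which used 0.6 µg of DNA digested partly with RsaI and AluI and partly with DraI. The median Cy5 spot signal was 21.5 to 25.8 times that of the negative control spots on the self arrays, 35.2 times on rot3-1, 43.4 times on zig-2, 34.0 times on Ler and 46.4 times on the digest array. On mag2-2 it was 2.98 times. The number of arrays limits the precision, and each mutant and Ler value came from 1 array with no replicate check, so the calls given here rest on size alone. A ratio at or below -1 on the log2 scale is called lower and a ratio at or above 1 is called higher.

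The self arrays gave the background for all other counts. With Col-0 DNA in both channels, the log2 ratios had an SD over probes of 0.13 ± 0.01 (mean ± SD, n = 3 arrays). At most 1 probe per array was lower, and 0, 6 and 0 probes were higher. No run of 2 or more neighbouring lower or higher probes was found on any of the 3 arrays. The log2 ratios of the 3 pairs of self arrays correlated across probes with r of 0.760, 0.665 and 0.643, and probes are not independent replicates. All 3 self arrays lay on a single slide that held no other group, so the slide and the group cannot be told apart.

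The first question was whether an array could place the DNA missing from a mutant line. The rot3-1 line, known for its short leaves, carries a defect in ROT3 (CYP90C1, a cytochrome P450 of brassinosteroid synthesis). On the rot3-1 array, 18 neighbouring probes on chromosome 4, from 17158457 to 17201184, had a mean log2 ratio of -6.60 ± 1.02 (SD over probes), which is not exact because 16 of them were at background in Cy5, and -2.55 under the normexp background correction. On the self arrays, the same probes averaged 0.02 ± 0.03 (SD, n = 3 arrays). ROT3 (AT4G36380) lay within this stretch, and a probe inside the gene had a ratio of -7.97. That probe was at background in Cy5, so its signal was at least 158-fold lower than in Col-0, and its ratio does not show a deeper loss than at other probes of the stretch.

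The 42.7 kb from the first to the last lower probe held 12 complete genes, 9 of them protein coding. Of these, 6 genes had a probe at least 200 bp inside the gene. CRH1 (AT4G36280) and CRT1 (AT4G36290), both microrchidia ATPases, had ratios of -7.55 and -7.80. BGAL3 (AT4G36360), a beta-galactosidase, had a median of -5.71 over 2 probes. D2HGDH (AT4G36400), a D-2-hydroxyglutarate dehydrogenase, had a median of -6.89 over 2 probes, and AT4G36270 had -7.19 over 2 probes. The nearest unaffected probes ended at 17156300 on the left and began at 17203026 on the right, with ratios of -0.04 and -0.04, so the missing stretch was at most 46.7 kb long. The 16 probes at background gave lower bounds of 12.0-fold to 158-fold. The other 2 were 29.5-fold and 119-fold lower than in Col-0.

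On the zig-2 array, 24 neighbouring probes on chromosome 5, from 15787649 to 15852753, had a mean log2 ratio of -5.91 ± 1.43 (SD over probes), and -2.31 under normexp. The zig line is known for zigzag stems and weak shoot gravitropism, and ZIG encodes the vesicle SNARE VTI11. The same probes averaged 0.02 ± 0.01 (SD, n = 3) on the self arrays. The flanking probes at 15783830 and 15855111 had ratios of 0.16 and 0.11, which limits the stretch to 71.3 kb. Of the 24 probes, 16 were at background in Cy5, so the mean is not exact, with lower bounds of 19.0-fold to 187-fold. The other 8 were 3.69-fold to 74.1-fold lower. The probe at the right end, starting at 15852694, had the weakest ratio of the stretch, -1.88. The file positions there differ from those of the annotation, so no gene is named in this stretch.

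On the mag2-2 array, 7 neighbouring probes on chromosome 3, from 17591960 to 17608008, had a mean log2 ratio of -2.39 ± 0.39 (SD over probes). MAG2 is known to act in the export of seed storage proteins from the endoplasmic reticulum. The self arrays averaged -0.01 ± 0.03 (SD, n = 3) at these probes. The nearest flanking probes above background in Cy5, at 17587982 and 17614959, had ratios of 0.35 and -0.28, which limits the stretch to 27.0 kb. A probe between them, at 17611341, was at background and is left out of this limit. The 5 probes above background in Cy5 were 5.21-fold to 7.57-fold lower than in Col-0, and the other 2, at background, gave lower bounds of at most 4.46-fold. This array was the dimmest of the 8, and no gene is named in the stretch, for the same reason as on chromosome 5. Under normexp the mean was -1.33, and the stretch was called as 2 runs that kept 5 of its 7 probes.

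**Figure D1:**
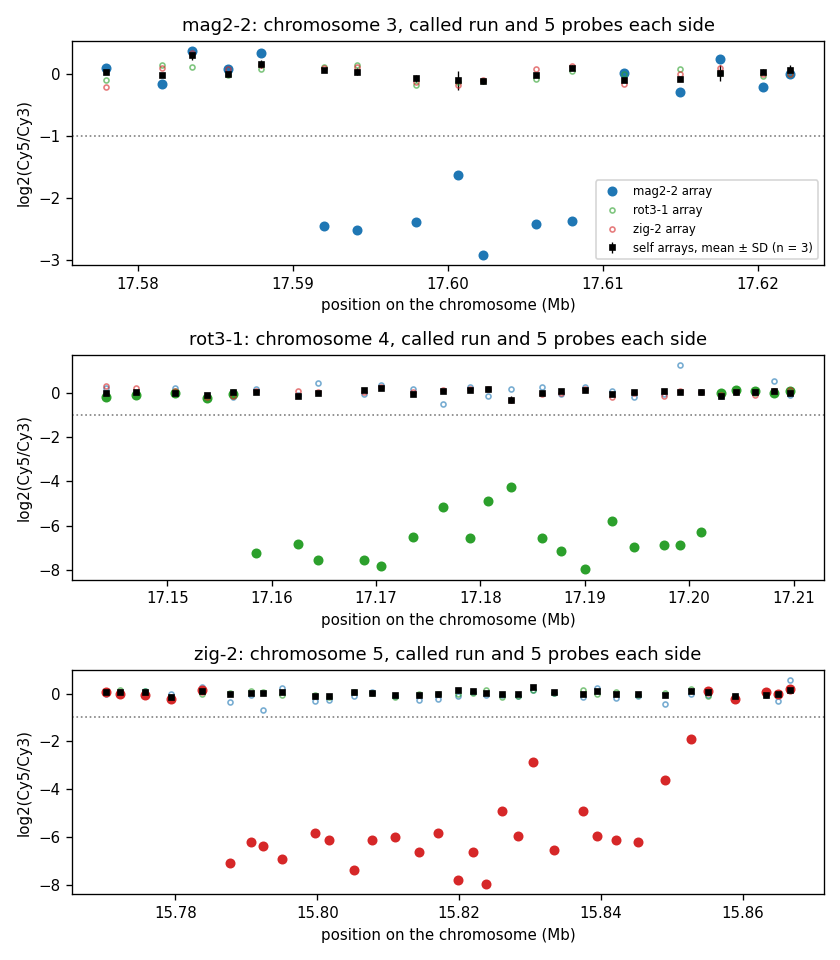
log2(Cy5/Cy3) of each probe against its position (Mb) at the stretch called lower on mag2-2 (top), rot3-1 (middle) and zig-2 (bottom), with 5 probes on each side. Filled circles are the line named in the panel, open circles the other 2 mutant lines, black squares the mean of the self arrays with SD bars (n = 3, 2 at 1 probe), and the dotted line marks -1, with means of the filled circles inside the stretches of -2.39, -6.60 and -5.91.

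Each of the 3 stretches was low on its own line's array alone among the mutant arrays. At the 18 probes of the rot3-1 stretch, mag2-2 averaged 0.12 and zig-2, which shared the slide with rot3-1, averaged 0.02. At the 24 probes of the zig-2 stretch, mag2-2 averaged -0.12 and rot3-1 averaged 0.01. At the 7 probes of the mag2-2 stretch, rot3-1 averaged -0.03 and zig-2 averaged 0.01. Ler, by contrast, averaged -0.77 at the zig-2 stretch, -0.08 at the rot3-1 stretch and -0.01 at the mag2-2 stretch.

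Outside these stretches, lower probes were few and isolated. On rot3-1, 20 probes were lower, of which 2 lay elsewhere in the genome. On zig-2, 33 were lower and 9 lay elsewhere. On mag2-2, 101 were lower and 94 lay elsewhere, none of them next to another. Each mutant array thus had 1 run of lower probes. Random reordering of its probes gave on average 0.009 runs for rot3-1, 0.026 for zig-2 and 0.235 for mag2-2, and at most 1, 2 and 3, so the number of runs alone does not set the arrays apart. Their length does, since the longest run in 1000 reorderings held 2, 2 and 3 probes, against 18, 24 and 7. This comparison of lengths was added after the data were seen. The mag2-2 count of lower probes depends on the choices made, and was 6 with normexp, 9 at a threshold of -1.5 and 1294 at -0.5. With the mean of the self arrays subtracted at each probe, the mag2-2 count was 68, and it was 65 when self replicate 3 was left out of that mean.

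At the threshold of 1, higher probes outnumbered lower ones on the mutant arrays, with 209 on mag2-2, 50 on rot3-1 and 128 on zig-2. On mag2-2 and rot3-1 this turned under other choices. On mag2-2 there were 17 higher and 82 lower probes without those that hold an RsaI or AluI site, an alternative chosen after seeing the data, and 1200 higher and 1294 lower at a threshold of 0.5. On rot3-1 there were 11 higher and 19 lower at 1.5. On rot3-1 they formed no run. On zig-2 they formed 10 runs of 2 or 3 probes, with 0.384 on average and at most 4 after reordering. Of these, 1 run on chromosome 3 held a probe inside AT3G22125 (mean of the run 1.89, self arrays 0.33) and 1 on chromosome 4 held a probe inside AT4G04070 (mean 2.04, self arrays 0.31). Another 6 lay on chromosome 2 between 3297828 and 6735116. The remaining 2 lay on chromosome 1 between 15290581 and 15405607, within 2 Mb of the centromere. The first of the chromosome 2 positions falls in a stretch of bright probes that was also raised on the self arrays, described under other observations. Whether these runs are gains in zig-2 was not tested. On mag2-2 there was 1 run of 4 probes on chromosome 2, from 3485125 to 3495430, with a mean of 1.13, where the self arrays averaged 0.56.

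The Ler array asked how the genome of a natural accession differs from Col-0. Of 42490 probes, 4699 were lower in Ler, or 11.1% (95% Wilson interval 10.8% to 11.4%, which covers counting over probes only). Another 393 were higher, or 0.925% (0.838% to 1.02%). Of the higher probes, 39.7% held an RsaI or AluI site, against 18.6% of the lower probes and 19.8% of all probes. Whether cutting at such sites raised ratios on Ler was not tested. The lower probes formed 744 runs of 2 or more neighbours, against 463 on average and at most 513 in 1000 random reorderings. These runs held 49.2% of the lower probes. The higher probes formed 26 runs, against 3.56 on average after reordering. A probe of 60 bases does not tell missing DNA from a changed sequence. Of the lower probes, 876 were at background in Cy5.

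Of the 15 longest lower runs, 11 were centred within 2 Mb of a centromere and 4 lay farther away. On chromosome 3, 19 probes from 14473478 to 14537614 averaged -3.89, and 17 probes from 14549793 to 14641881 averaged -3.20. On chromosome 4, 19 probes from 5870947 to 5922784 averaged -4.04. On chromosome 2, 16 probes from 4422603 to 4492512 averaged -3.49. On chromosome 1, 16 probes from 12766298 to 12810565 averaged -2.35, and a probe inside AT1G35030 in this run had -1.27. Of the 15 longest runs, 6 lay on chromosome 3, 4 on chromosome 2, 3 on chromosome 4, and 1 each on chromosomes 1 and 5. The longest higher run held 10 probes on chromosome 1, from 9569516 to 9591909, with a mean of 2.23 against 0.02 on the self arrays. It covered AT1G27570, whose 3 probes had ratios of 1.85, 2.68 and 2.24. The next 4 higher runs held 3 probes each, 3 of them on chromosome 3 and 1 on chromosome 5.

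The share of lower probes was larger within 2 Mb of a centromere than on the arms, 23.3% (22.0% to 24.6%) of 4160 against 9.73% (9.44% to 10.03%) of 38330. The share of higher probes differed the same way, 2.26% (1.85% to 2.76%) against 0.780% (0.697% to 0.873%). On the self arrays, 0 of 4101, 4096 and 4093 probes near centromeres were lower. The share near the centromere was 36.9% on chromosome 3, 23.4% on chromosome 4, 20.8% on chromosome 2, 19.4% on chromosome 1 and 16.3% on chromosome 5. The arms ranged from 8.99% on chromosome 2 to 10.5% on chromosome 5. Among 121 bins of 1 Mb the median share was 9.61%. The extremes were 63.1% in the bin that starts at 13 Mb on chromosome 3 and 1.83% in the bin that starts at 4 Mb on chromosome 5.

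**Figure D2:**
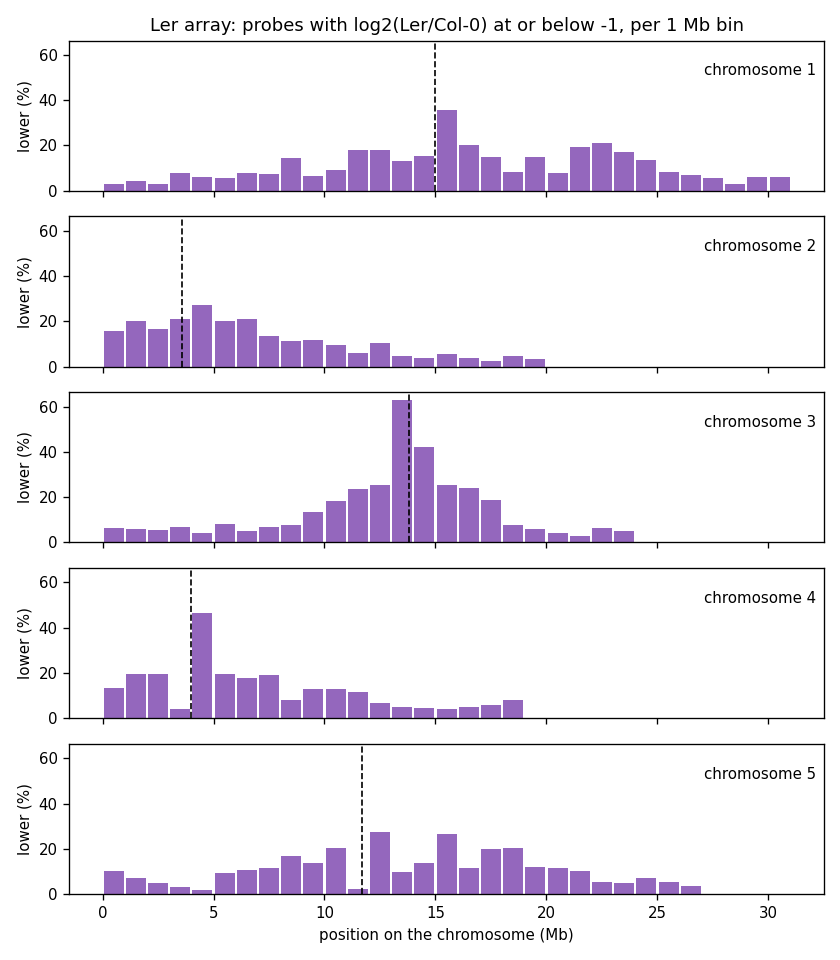
Percent of probes with a log2(Ler/Col-0) ratio at or below -1 in each 1 Mb bin (vertical axis) along chromosomes 1 to 5 (horizontal axis, Mb), with dashed lines at the approximate centromeres. The highest bar is the bin at 13 Mb on chromosome 3 with 63.1%, and the median bin has 9.61%.

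Genes of known natural variation showed a mixed picture. Of 24 listed genes, 11 had a probe that could be placed inside the gene. Low values were found in disease resistance genes. RPP4 (AT4G16860) had probes with log2 ratios of -4.71 and -5.44, at least 16.0-fold and 26.2-fold lower in Ler, beside another probe at 1.05. RPP5 (AT4G16950) had probes at -1.59, -0.89 and 1.38. RPS2 (AT4G26090), another resistance gene, had -0.04. Of the glucosinolate genes, AOP2 (AT4G03060) and AOP3 (AT4G03050) were higher in Ler with 1.09 and 2.07, MAM1 (AT5G23010) had 0.54 and 0.70, and MAM3 (AT5G23020) had -0.13. Of the flowering genes, FLC (AT5G10140), a repressor of flowering, had 1 higher probe at 2.17 between probes at 0.19 and -0.08. HUA2 (AT5G23150) had -0.11 and 0.39, and the blue-light receptor gene CRY2 (AT1G04400) had 0.22. In all, 3 of the 11 genes had a lower probe, 5 had a higher probe and 5 had neither, with RPP4 and RPP5 counted under both lower and higher. Over the 62 probes of the genes selected for Ler, the means of the self arrays lay between -0.30 and 0.25. Of the 20 lower probes among them, 9 were at background in Cy5, so their log2 ratios are not exact.

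The share of lower probes was smaller among probes placed inside a gene than among the other probes of the same windows, which include probes near gene ends. In the windows where genes could be placed, 6.77% (6.24% to 7.34%) of 7978 probes inside a gene were lower, against 11.3% (10.7% to 11.9%) of the 12012 others. At least 1 lower probe was found in 510 of 6298 genes. Probes inside pseudogenes, a group chosen after its values were seen, were lower in 36 of 182 cases (19.8%, 14.6% to 26.2%), against 6.44% (5.91% to 7.01%) of 7700 probes inside protein-coding genes.

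Gene classes set by name were small here. Against 10000 random probe lists matched on Cy3 signal, the planned comparison was of the class median. The percentile of the share of lower probes was not planned. It was 99.6 for receptor-like genes (16.4%, median of random lists 5.97%). For the 10 ribosomal protein probes it was 97.6 (30.0%, median of random lists 0%, although 6.77% of all probes inside a gene were lower). In the other classes set by name with 10 or more probes it lay between 22.64 and 84.85. By the median ratio, none of the 6 classes with 10 or more probes had a median below the 5th percentile of the random lists. The receptor-like class came nearest. Its median of 0.02 lay at percentile 5.17 (5.83 with another draw of random lists), with 11 of 67 probes lower (interval 9.42% to 27.1%), while the random lists had a median of 0.08. This percentile was 2.17 with normexp and 33.6 with the self mean subtracted (5.59, 29.3 and 49.2 without self replicate 1, 2 or 3), and that of the cytochrome P450 median was 3.89 with the series matrix values. CRK25 (AT4G05200) and CRK31 (AT4G11470), cysteine-rich receptor-like kinases, had -4.29 and -2.92, and PERK2 (AT3G24400) had -2.59.

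Of the other classes with at least 10 probes, cytochrome P450 genes had 6 of 50 probes lower and a median at percentile 23.3. The lowest was CYP77A5P (AT3G18270) at -4.87, at background in Cy5 and at least 24.2-fold lower. It was followed by CYP81D5 (AT4G37320) at -4.14 and CYP79B2 (AT4G39950), which acts in indole glucosinolate synthesis, at -3.61. MADS-box genes had 1 of 20 probes lower (percentile 23.1), namely AGL104 (AT1G22130) at -3.68, followed by GOA at -0.61 and AGL21 at -0.32. Ribosomal protein genes had 3 of 10 lower (percentile 29.3), among them RPL21C at -2.94 and RPL16B at -2.86. Both of these probes were at background in Cy5, at least 5.11-fold and 4.99-fold lower. Proteasome genes had 2 of 16 lower (percentile 74.3), RPT2a at -2.28 and RPN8A at -1.94, with PAA2 at -0.32. Tubulin or actin names had 2 of 24 lower (percentile 7.02). The probe of TUB8 (AT5G23860), a beta-tubulin gene, was at -5.10 and at least 23.2-fold lower, and ADF11 had -0.78. AT5G20840 had a median of -0.20 over 2 probes, of which neither was lower.

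The smallest classes had too few probes for a percentile. Of the resistance gene class, 2 of 9 probes were lower, 1 of them in RPP5, and EDR2 (AT4G19040) had a median of -0.39. Of the UDP-glycosyltransferases, 1 of 8 was lower, UGT88A1 (AT3G16520) at -6.50 and at least 67.9-fold lower, with UGT73B2 at -0.50 and UGT73B1 at -0.13. Of the F-box genes, 1 of 3 was lower, AT1G15670 at -2.09 and at least 3.07-fold lower, while AFB3 had 0.32 and AFB4 had 0.44. No probe was lower among 3 defensin-like (LCR17, LCR38 and LCR11, between -0.07 and 0.10), 3 TRAF/MATH (BPM5 and BPM4, medians 0.03 and 0.10), 3 histone (HTA2, HON4 and HTA4, between 0.14 and 0.22) and 5 photosystem probes (the lowest HCAR, PSAL and PSAK at -0.06, 0.07 and 0.20). No probe could be placed in a transposon gene.

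The next comparison asked whether the mutant arrays showed the Ler pattern, as they would in a line that holds Ler segments. The 4699 probes lower on Ler had medians of -0.05 on mag2-2, 0.00 on rot3-1 and -0.03 on zig-2, against -0.02, -0.02 and 0.00 on the self arrays. On rot3-1, 0.0851% (0.0331% to 0.219%) of them were at or below -0.5, within the range of 0.0648% to 0.150% on the self arrays. On zig-2 it was 0.958% (0.717% to 1.28%) and on mag2-2 4.97% (4.38% to 5.63%), where 0.609% and 2.82% of all other probes also reached -0.5. With the mean of the self arrays subtracted, the shares were 0.533% (0.361% to 0.785%) on zig-2 and 3.52% (3.03% to 4.09%) on mag2-2, against 0.376% and 2.14% of all other probes. Among 98 bins of 1 Mb with at least 20 such probes (97 on self replicates 2 and 3), the lowest bin median was -0.19 on mag2-2, -0.08 on rot3-1 and -0.13 on zig-2. On the self arrays it was -0.10, -0.09 and -0.08.

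The digest array compared Col-0 DNA cut in different ways. Cy3 held DNA cut with RsaI and AluI, which recognise GTAC and AGCT, and Cy5 held that digest mixed with DNA cut by DraI, which recognises TTTAAA. The 7508 probes with an RsaI or AluI site and no DraI site had a median log2 ratio of 0.92 (quartiles 0.31 and 1.63). The 4372 probes with a DraI site alone had -0.49 (quartiles -0.71 and -0.17), the 887 with both had 0.01 and the 29713 with neither had -0.03. On the self arrays the 4 medians averaged 0.00 ± 0.02, -0.02 ± 0.00, -0.01 ± 0.02 and 0.00 ± 0.00 (SD, n = 3). Among random lists matched on Cy3 signal, the first group lay at percentile 100 and the DraI group at percentile 0. The group with both sites also lay at percentile 0. The group with neither lay at 0.01, although its median of -0.027 was near the -0.024 of the random lists. At these list sizes the percentile does not tell a large difference from a small one. Of the 3916 higher probes, 93.9% held an RsaI or AluI site, against 19.8% of all probes. Of the 232 lower probes, 81.5% held a DraI site, against 12.4% of all probes.

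RsaI and AluI sites gave similar medians alone, 0.79 over 3387 probes and 0.96 over 3777 probes. Probes with 1, 2 and 3 such sites had medians of 0.83, 1.74 and 2.33. Of the genes with at least 2 probes, the highest medians were in AT5G17270 at 3.40, XIA (AT1G04600), a myosin gene, at 2.52, UBP16 (AT4G24560), a ubiquitin protease gene, at 2.49, NDB1 (AT4G28220) at 2.43 and GYRB1 (AT3G10270), a gyrase subunit gene, at 2.39. In these 5 genes, 13 of 14 probes held an RsaI or AluI site. The lowest medians were in AT4G11030 at -0.79, AT4G38120 at -0.75, AT2G02635 at -0.74, AT2G05642 at -0.74 and AT1G33110 at -0.59, where 9 of 11 probes held a DraI site. Without the probes that were dim in Cy3 on a self array, the difference between probes with an RsaI or AluI site and those with none fell from 0.94 to 0.79.

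**Figure D3:**
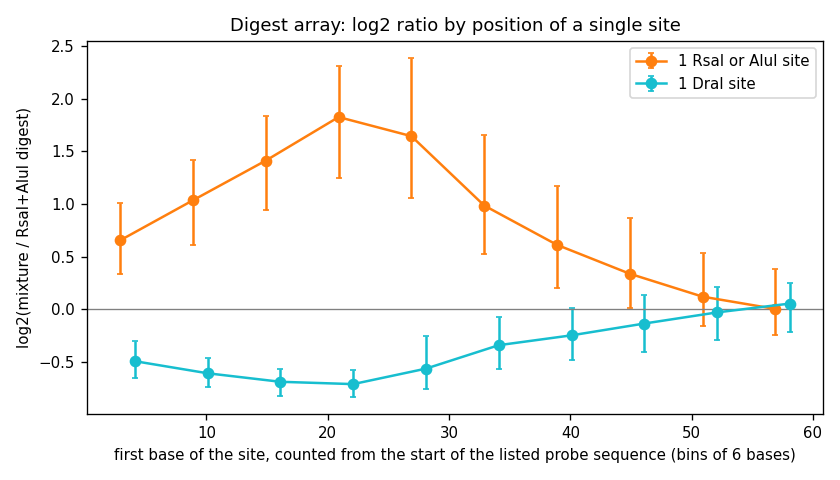
Median log2 ratio of the mixture over the RsaI and AluI digest (vertical axis) for probes with a single restriction site, by the first base of that site counted from the start of the listed probe sequence (horizontal axis, bins of 6 bases). Points are medians over probes and bars run from the lower to the upper quartile. RsaI or AluI sites peak at 1.83 and DraI sites reach -0.71, both in the bin from base 19 to 24.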

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

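The alternatives that leave out probes with an RsaI or AluI site, or with a shared sequence, were chosen after seeing the data. Of 225 comparisons of 24 main results with an alternative, 158 stayed within the spread or interval of the main value, or within 1.5 times for counts, and 67 moved. A reversal could be labelled only for the stretch means and the digest differences, where 0 reversed. The balance of higher and lower probes, which turned on mag2-2 and rot3-1, was not among these main results. The 158 include 4 limma counts on mag2-2 and Ler, those on zig-2 and that of lower probes on rot3-1. The 67 include the limma count of higher probes on rot3-1. These limma counts are not read because the spread assumed by limma was not shown to hold on these arrays. The spread for the stretch means is the SD over the self arrays. The cause was not tested unless stated. Of 64 comparisons of the share of lower probes in single classes, 63 stayed, and the share in coding genes moved to 7.47% with normexp. The percentiles of the class medians varied more, from 2.17 to 49.2 for receptor-like, 3.89 to 54.0 for cytochrome P450 and 19.6 to 84.8 for MADS-box genes.

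A threshold of 1.5 gave 9 lower and 42 higher probes on mag2-2, and 11, 53 and 135 higher probes on rot3-1, zig-2 and Ler. A threshold of 0.5 gave 1294 lower and 1200 higher probes on mag2-2, 62 and 315 on rot3-1, 275 and 459 on zig-2, and 7191 and 1378 on Ler, with 49 lower runs on mag2-2, 2 on zig-2 and 1234 on Ler. With runs of at least 3 probes, Ler had 337. These counts move with the threshold by construction.

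With normexp, the self SD was 0.18, mag2-2 had 6 lower and 35 higher probes and rot3-1 had 76 higher probes. The lower runs numbered 2 on mag2-2, 3 on rot3-1 and 2 on zig-2, each overlapping the main stretch, of which 5 of 7, 16 of 18 and 23 of 24 probes were kept. The stretch means were -1.33 on mag2-2, -2.55 on rot3-1 and -2.31 on zig-2. Loess gave -6.48 on rot3-1 and -5.67 on zig-2. The number of gene classes below the 5th percentile rose from 0 to 1 with normexp and to 1 with the series matrix. The digest differences became 0.80 for RsaI or AluI and -0.55 for DraI. Loess gave a self SD of 0.11 and an RsaI or AluI difference of 0.85, and the filter on dim probes gave 0.79.

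Subtracting the self mean gave a zig-2 stretch mean of -5.93, 32 higher probes on rot3-1, digest differences of 0.98 and -0.43, and shares at or below -0.5 among Ler-lower probes of 3.52% on mag2-2 and 0.533% on zig-2. With each self replicate left out, the ranges were -2.39 to -2.36 and -5.93 to -5.92 for the stretch means of mag2-2 and zig-2, 65 to 71 lower probes on mag2-2, 31 to 32 higher probes on rot3-1, 0.97 to 0.99 for RsaI or AluI and -0.44 to -0.43 for DraI. The lowest, 65, came without self replicate 3. The limma count of higher probes on rot3-1 also moved, but is not read. Without probes holding an RsaI or AluI site, mag2-2 had 17 higher, rot3-1 12 lower and Ler 237 higher probes. Fewer probes are counted by construction, since 19.8% of all probes held such a site. The share was larger among the called probes, at 91.9% of those higher on mag2-2 and 39.7% of those higher on Ler. Construction alone therefore does not account for these 2 falls. On rot3-1 it was 40.0% of the 20 lower probes, most of them in a single stretch. Near centromeres and on the arms, the Ler shares were 30.1% and 10.4% within 1 Mb, 21.0% and 8.88% within 3 Mb, 18.7% and 6.88% at -1.5, and 31.4% and 15.3% at -0.5.

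The share of higher among called probes was 67.4% on mag2-2, 85.4% with normexp, 82.4% and 48.1% at thresholds of 1.5 and 0.5, and 17.2% without probes holding an RsaI or AluI site, so its direction depends on the choice. On rot3-1 it was 71.4%, 82.6% with normexp, 36.7% at 1.5 and 58.2% with the self mean subtracted (54.2% to 59.6% with a replicate left out). Signal over negative control spots was lowest on mag2-2, at 2.98 in Cy5. No paired analysis was possible because no sample was measured on more than 1 array. Probes matching the genome once and sites within 50 bases were not run for want of a genome, and a slide block was not run since all self arrays shared a slide.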

Other observations

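All tests of explanations in this part were chosen after the results were seen.

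A run of 10 lower Ler probes on chromosome 4, from 11047994 to 11077384, was made of a single probe sequence repeated every 3259 bp. The mean was -2.07 ± 0.05 (SD over probes) in Ler and 0.31 on the self arrays, and the flanking probes had 1.31 and 1.12. The span held 14 protein-coding genes, from AT4G20530 to AT4G20610. Of the 744 lower runs on Ler, this was the 1 run with a single distinct sequence.

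At the numbering shift found for its window, -10900 bp, MAG2 (AT3G47700) lay inside the mag2-2 stretch on chromosome 3, and with no shift it lay outside. ZIG (AT5G39510) lay inside the zig-2 stretch on chromosome 5 both with no shift and at its window's shift of -17100 bp. At these shifts the stretches held 4 and 15 protein-coding genes.

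On rot3-1 and zig-2, 45 of the 50 and 128 higher probes were the same. The 2 arrays shared a slide, Col-0 DNA in Cy3, the amount of 0.6 µg and the mixed digest, so their lists are not independent. Their medians were 1.25 and 1.72, and 0.11 on Ler.

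On the digest array, the median by position of an RsaI or AluI site, a division chosen after seeing the data, peaked at 1.83 for sites starting at bases 19 to 24 and was 0.66 in the first 6 bases and 0.00 in the last 6.

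Of the 209 probes higher on mag2-2, 91.9% (87.4% to 94.9%) held an RsaI or AluI site, against 19.8% of all probes. This argues against noise that falls alike on probes with and without such sites. Without the probes dim in Cy3 on a self array, 141 higher and 98 lower probes were left, against 209 and 101. Of the 101 lower probes, 18.8% held such a site, so the excess of sites was on the higher side alone. Noise that is larger at dim probes was not separated from the sites and stays open. Extra copies of segments of several probes would form runs, but 205 of the 209 lay in no run, with 1 run where reordering gave up to 5. That run held 4 probes, against at most 3 in reordering, so extra copies could account for it and stay open, though the self arrays, with Col-0 DNA in both channels, also averaged 0.56 there, which goes against them. Over all 209 probes the median on the digest array was 2.21, so less complete cutting by RsaI and AluI in the mag2-2 DNA than in its Col-0 DNA may account for most of the 209. The labels name no enzyme for this array, and no biological explanation beyond extra copies was tested.

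The mag2-2 stretch was shallower than those of rot3-1 and zig-2, with a median residual signal of 18.7%, while 16 of 18 and 16 of 24 probes of the other stretches were at background in Cy5, so no residual is given there. If Cy5 lay at the floor of the dim array, the log2 ratio would fall by about 1 for each doubling of Cy3, and over the 7 probes the slope was -0.11 (-0.16 to 0.06 with any 1 probe left out), against -0.93 on rot3-1 and -1.03 on zig-2, which argues against the floor as the cause of the stretch's depth, though 2 of the 7 probes were at background. Wild-type DNA in the sample could give a like fold at each probe, and the measured folds had a median of 5.35 and ran from 5.21 to 7.57. With 1 array this stays open, as does a difference between the lines themselves, which was not tested.

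A stretch of 43 bright probes on chromosome 2, from 3247214 to 3364072, had medians of 0.69 on mag2-2, 0.73 on rot3-1 and 0.74 on zig-2, 0.32 to 0.42 on the self arrays and 0.02 on Ler. A dye effect of bright probes as the whole cause is argued against by the difference from other equally bright probes, at least 0.42 on the mutant arrays and at most 0.11 on the self arrays. This difference was 0.31 on the digest array and -0.31 on Ler, so a value above those of the self arrays also arose without mutant DNA. More organelle DNA in the mutant samples could raise the stretch, but the digest array, with Col-0 DNA in both channels, also had 0.56. No organelle probe elsewhere could be named, which keeps this open.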
